A study of Mus musculus with 9 samples.

How the data were processed

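Gene expression was measured with single-colour microarrays in mouse retinal organoids, which are retina-like tissues grown in floating culture from ES or iPS cells by quick reaggregation. There were 9 samples from 3 cell lines, wild type (WT), Bhlhb4 knockout (B4KO; the gene is now named Bhlhe23) and Islet-1 knockout (Isl1KO), each sampled once at differentiation day 10, 16 and 23 (DD10, DD16 and DD23). Each sample pooled 5 organoids, per the labels' protocols, so no combination of line and day had a replicate, and the number of arrays limits the precision of every value.

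The spot intensity of each array was extracted with Agilent Feature Extraction 12.0.3.1, per the file headers. The processed intensity was background-subtracted and detrended, dim spots were set to a substitute value, and no normalization between arrays was applied, per the file headers. Raw mean and local background intensity and 0 or 1 flags for saturated, outlying and well-above-background spots were given beside it, per the file headers. The deposited value table had a 75th percentile over all spots of 1.00 on each array. For the gene spots above 1, from 15500 to 15540 per array, it held the processed intensity divided by a constant per array, as a check of the values showed. Dimmer spots were not part of that check. Probe coordinates were those of the array design, build mm9, per the file headers.

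The processed intensity of each spot was averaged over spots of the same probe, and 102 probes with an outlier flag on all their spots of at least 1 array were left out. Of 56605 different gene probes, 32994 were matched by RefSeq accession to a RefSeq table of assembly GRCm38.p6, which was used for names only, and 23611 kept the name in the file. Values were log2 intensity minus the log2 75th percentile of the array. For each gene the brightest probe that was well above background on at least 3 of the 9 arrays was used, which left 23594 genes. Analyses were run in R 4.3.3 with data.table (version 1.17.8).

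Genes were tested with limma 3.58.1, with genotype and day as additive terms in 1 model of all 9 arrays (4 residual degrees of freedom, 2.01 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The comparisons were B4KO with WT, Isl1KO with WT, Isl1KO with B4KO, DD16 with DD10 and DD23 with DD16, with an F test over genotypes and another over days. Standard errors are those of this model. With no replicates the spread is the departure from additivity, that is, the interaction of line and day plus noise. A second model with a term for DD23 in each knockout (2 residual degrees of freedom) tested whether the difference from WT at DD23 departed from its mean over DD10 and DD16. Differences of a knockout from WT at a single day compare 2 arrays and have no test. Where a group was well above background on none of its arrays, the fold is given as a lower bound ("at least"), computed with each dim value raised to the lowest signal that was well above background on its array.

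Gene lists, 31 in number, were tested with camera of limma, with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 31 lists within a comparison. They were rod and ON cone bipolar cells, OFF cone bipolar cells, bipolar cells shared, rod photoreceptors, photoreceptors shared, cone photoreceptors, ribbon synapse, Mueller glia, retinal progenitor cells, neurogenic progenitor cells, retinal ganglion cells, amacrine cells, starburst amacrine cells, horizontal cells, retinal pigment epithelium, lens, forebrain, mesenchyme, pluripotent stem cells, endoderm, skeletal muscle, endothelium and blood cells, neural crest and oligodendrocyte lineage, cell cycle, hypoxia and glycolysis, integrated stress and heat shock, immediate early genes, p53 targets, interferon response, imprinted genes and Y-linked genes. At single days, the median difference of a list's members that were well above background on at least 1 of the 2 arrays was set beside the medians of 10000 random lists of the same size matched on mean signal in 20 bins; this reading of a measured member was chosen after seeing the data. A further 6 lists, for the retinoic acid response, hindbrain and spinal cord cells, Hox genes of cluster b, Hox genes outside it, paternally expressed genes beside Meg3 and other imprinted genes, were written after the first results were seen and before their own tests.

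Named genes were both targeted genes; for each comparison the 6 largest rises and 6 largest falls that passed the threshold, went the same way in all 3 matched pairs of arrays and had an established symbol; a fixed panel of retinal marker genes; and the 2 largest rises and falls of each list described. Some of the named genes are not reported here. The lists, the panel, the models, the thresholds and the alternatives were fixed before the data were examined, except where the text says otherwise. Alternatives were quantile normalization, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes, a filter on all 9 arrays, the mean of a gene's probes, limma with trend and robust options, models without the day or genotype term, each array, each day or the slide of B4KO left out, and a linear late term; removal of the trend over probe brightness and GC content, cyclic loess and list medians with dim members at their bound were added after seeing the data.

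The steps were tested on simulated data made from the real arrays, 23594 genes with known changes added to the comparison of Isl1KO with WT. The additive model recovered 70.1% of 67 genes altered by a log2 of 1, 85.1% of 67 altered by 2 and 97.0% of 66 altered by 4, and 4.55% of its 176 calls were unaltered genes. The simulated noise was independent between genes, with its size drawn at random for each gene and no interaction of line and day. These shares may overstate what the real comparison could detect. There Meg3 (5.69), Rian (4.24) and Mirg (4.20) did not pass over all genes. The late term recovered none of the genes altered by 1 or 2 and 50% of those altered by 4. For a list of 20 genes shifted by a log2 of 1, camera with the preset correlation gave p = 4.44e-34. Of 100 unshifted lists 2 gave p under 0.05. Since the simulated noise was independent between genes, this does not show how often camera errs on lists whose genes vary together.

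The file names place the 3 B4KO arrays on 1 slide and the WT and Isl1KO arrays on another, each scanned separately, and place each day in its own column of arrays. B4KO and slide therefore cannot be told apart, nor can day and column, and p-values for B4KO do not include the spread between slides. With 1 line per genotype, no p-value for a genotype includes the spread between lines of the same genotype. Comparisons within the slide of WT and Isl1KO are given where they can be had.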

Results

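RNA from mouse retinal organoids of 3 lines was measured on 9 single-colour arrays, with 1 sample per line at DD10, DD16 and DD23. The lines were WT, B4KO and Isl1KO, the knockouts having been made to lower the number of bipolar cells, the interneurons that carry signals from photoreceptors to the inner retina. Each array held 59305 gene spots, of which between 57.3% (WT at DD16) and 67.8% (Isl1KO at DD23) were well above background; none was saturated. The 75th percentile of the processed intensity ranged from 897 (B4KO at DD16) to 1138 (Isl1KO at DD10). The largest component of variation over genes (58.9% of the variance) ordered the arrays by day and the next (17.3%) set B4KO apart. Across genes within a day, which are not independent replicates, Isl1KO and WT correlated at Pearson's r of 0.988 to 0.991, and B4KO with the other lines at 0.978 to 0.983.

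Isl1, a LIM homeodomain factor of bipolar, ganglion and starburst amacrine cells, gave less signal in the Isl1KO samples than in WT with the probe from 117099604 on chromosome 13, by 1.57-fold at DD10, 3.69-fold at DD16 and 2.99-fold at DD23. A second Isl1 probe, from 117088774, differed from WT by a log2 of 0.37, -0.76 and -0.26 on those days, so the probes did not read alike. Isl1 signal stayed well above background in Isl1KO on every array. Bhlhe23, a basic helix-loop-helix factor of rod bipolar and amacrine cells, was dim in all lines (chromosome 2, from 180509639). In B4KO it differed from WT by -0.22 at DD10 and was at least 3.41-fold lower at DD16 and at least 1.12-fold lower at DD23. Isl1KO samples also had less Bhlhe23 signal than WT at DD16 (3.31-fold) and DD23 (at least 1.80-fold). Both genes were lower in the line named for them at the later days, by values of single arrays with no replicate check. The Bhlhe23 fall was not particular to B4KO. Taken without bounds, it was -2.05 and -2.09 at DD16 and DD23 in B4KO, and -1.73 and -2.01 in Isl1KO. Part of it may come from the slide, since E1A_a107, a spike-in RNA of similar brightness, read -0.78 on the slide of B4KO. These values therefore do not establish either knockout. The position of the engineered deletions is not given in the sources used here, and a probe outside a deleted part checks nothing.

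**Figure D1:**
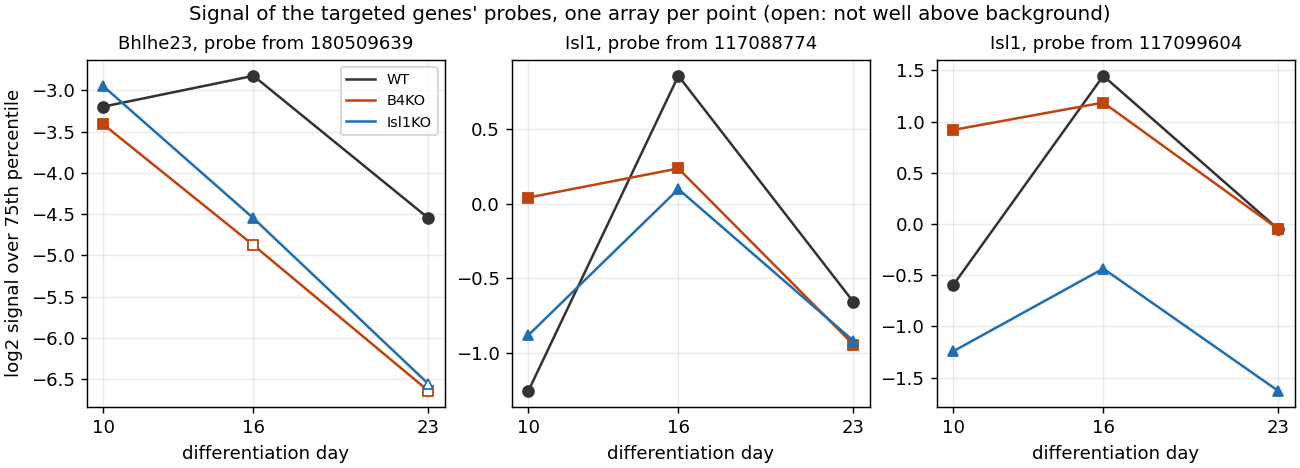
Log2 signal relative to the array's 75th percentile (y axis) of the Bhlhe23 probe and both Isl1 probes by differentiation day (x axis) in each line, with open symbols where the signal was not well above background. Isl1KO lay 1.88 below WT at DD16 for the Isl1 probe from 117099604, while the other Isl1 probe lay 0.76 below.

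Between DD10 and DD16, in the comparison that asks how the organoids changed as retina formed, photoreceptor genes came on in all 3 lines. Nrl, the factor that sets rod fate, was at least 67.6-fold higher, and Crx, which drives photoreceptor genes in rods and cones, rose 17.5-fold (log2 4.13, SE 0.19, n = 3 arrays per day). Transducin subunits rose with them, Gngt2 of cones by 169-fold (7.40, SE 0.27) and Gngt1 of rods by at least 60.4-fold. Hoxb8, Hoxb7 and Hoxb6, patterning genes best known from the hindbrain and trunk, were at least 58.5-fold, at least 52.2-fold and at least 35.8-fold higher. Falls were led by Gmnc, a regulator of multiciliated cells (at least 47.2-fold lower), the chemokine Cxcl5 (-5.56, SE 0.31), Dmrta1 (at least 9.32-fold), Aldh1a7 (-4.81, SE 0.24), the Wnt activator Rspo1 (-4.80, SE 0.32) and Wnt3a (-4.78, SE 0.26).

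Among cone photoreceptor genes 11 of 12 tested rose at DD16 and 1 did not pass (12 rose adjusted over the list alone). Their median was 2.56, with adjusted p = 5.49e-07 by camera, and adjusted p = 0.452 with an estimated correlation. Pde6c, the cone phosphodiesterase, rose by 5.19 and Gnat2 by 3.56. Genes shared by rods and cones rose in 19 of 25 and fell in 1 (21 and 2 adjusted over the list alone). Their median was 1.79, or 1.33 with dim members at their bound (adjusted p = 5.49e-07, and adjusted p = 0.452 with an estimated correlation). Pdc, the phototransduction regulator phosducin, rose by 7.02 and Samd7 was at least 24.6-fold higher, while Prom1 fell by 0.55. Of rod genes 5 of 16 rose and none fell, also when adjusted over the list alone. Their median was 0.29, or 0.42 with dim members at their bound (adjusted p = 0.0393, and adjusted p = 0.622 with an estimated correlation). Ribbon synapse genes rose in 9 of 13 and fell in 1, the same numbers adjusted over the list alone, led by the calcium channel subunit Cacna2d4 (at least 7.17-fold). Their median was 1.18 (adjusted p = 0.00199, and adjusted p = 0.452 with an estimated correlation). Otx2, which acts upstream of Crx, rose by 0.73.

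Neurogenic progenitor genes rose in 11 of 14 and none fell (11 and 1 adjusted over the list alone), among them Neurod4 by 4.38 and Olig2 by 3.43. Their median was 1.74 (adjusted p = 2.24e-05, and adjusted p = 0.452 with an estimated correlation). Of genes shared by bipolar cells 7 of 10 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.87 (adjusted p = 0.0413, and adjusted p = 0.452 with an estimated correlation). Gnb3, a G protein subunit also present in cones, rose by 4.53, Samsn1 was at least 14.0-fold higher, and Lrtm1 fell to no signal well above background. Ganglion cell genes, those of the retina's output neurons, rose in 8 of 16 and fell in 2, also adjusted over the list alone, with Isl2 higher by 4.03, Thy1 by 3.94 and Eomes lower (-1.84). Their median was 0.81 (adjusted p = 0.0413, and adjusted p = 0.452 with an estimated correlation). Pcp2, a marker of rod and ON cone bipolar cells, rose by 4.96 (31.2-fold, SE 0.32). In its list 6 of 14 rose and 2 fell, also adjusted over the list alone (median 0.64, or 0.36 at their bound; adjusted p = 0.0552). Trpm1, the ON bipolar channel that pigment cells also express, fell by 2.16 with the probe used, and its other probes had values from -0.18 to -3.70.

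Pigment epithelium genes fell in 7 of 14 and rose in 1, the same numbers adjusted over the list alone (median -0.86, adjusted p = 0.0023, and adjusted p = 0.452 with an estimated correlation). The pigment genes Slc45a2 and Oca2 fell by 3.47 and 2.76, and Ttr, which carries thyroxine and retinol and is also made by choroid plexus, rose by 2.37. Cell cycle genes fell in 17 of 29 and rose in 1 (21 and 1 adjusted over the list alone), led by Tyms (-1.25) and Mcm5 (-1.21). Their median was -0.63 (adjusted p = 3.97e-06, and adjusted p = 0.622 with an estimated correlation). Stress and heat shock genes rose in 10 of 12 and none fell (10 and 1 adjusted over the list alone), with the inducible chaperones Hspa1a and Hspa1b higher by 4.18 and 3.77. Their median was 1.51 (adjusted p = 0.000104, and adjusted p = 0.452 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 17 and fell in 1 (11 and 2 adjusted over the list alone), with Ndrg1 higher by 2.51 and Adm by 2.17. Their median was 0.32 (adjusted p = 0.00912, and adjusted p = 0.622 with an estimated correlation).

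In the limma test of DD16 with DD10, 5167 genes rose and 4439 fell of 23594 tested, and 1598 and 987 of these by at least 2-fold; 9605 of the 9606 went the same way in all 3 lines. Within the slide of WT and Isl1KO 4899 genes passed (2725 higher), and without the Isl1KO sample at DD10 or at DD16 5899 and 5917 did. Of the 31 lists 11 passed with the preset correlation, and within that slide too, and 0 with the estimated one. Day and array column cannot be told apart.

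From DD16 to DD23, in the comparison that follows maturation, the phototransduction genes of rods came on. The phosphodiesterase genes Pde6b and Pde6a rose 159-fold (7.32, SE 1.25, n = 3 arrays per day) and at least 13.3-fold, and Rcvrn, the calcium sensor recoverin, was at least 60.03-fold higher. Opn1sw, the short-wavelength cone opsin, rose 71.1-fold (6.15, SE 0.41) and Nr2e3, which represses cone genes in rods, 60.7-fold (5.92, SE 0.43). The largest falls were in Atoh7, the factor that makes progenitors competent for ganglion cells (-4.53, SE 0.39), Hoxb9 (at least 14.0-fold lower), Cyp26b1 and Cyp26a1, which degrade retinoic acid (-4.42, SE 0.49, and -3.96, SE 0.58), Dio3os (-3.95, SE 0.57, with other probes that fell less) and the progenitor gene Fgf15 (-3.71, SE 0.24).

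All rod genes tested had positive values and 12 of 16 rose, also adjusted over the list alone (median 2.67, adjusted p = 1.47e-07, and adjusted p = 0.281 with an estimated correlation). Genes shared by both photoreceptor types rose in 19 of 25 (21 adjusted over the list alone), such as the outer segment gene Rp1 by 5.01 and Crx by 1.52. Their median was 1.69, or 1.54 with dim members at their bound (adjusted p = 3.11e-09, and adjusted p = 0.281 with an estimated correlation). Cone genes rose in 10 of 12, also adjusted over the list alone (median 2.35, adjusted p = 2.1e-05, and adjusted p = 0.281 with an estimated correlation), with the cone arrestin Arr3 higher by 5.49 by the brightest of its probes. Ribbon synapse genes rose in 10 of 13 (13 adjusted over the list alone), among them Cacna2d4 by 2.20 and Cplx3 by 1.76. Their median was 0.99 (adjusted p = 2.95e-06, and adjusted p = 0.281 with an estimated correlation).

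Rod and ON cone bipolar genes rose in 8 of 14 and fell in 2, also adjusted over the list alone (median 0.85, adjusted p = 0.0108, and adjusted p = 0.281 with an estimated correlation). Gng13, a G protein subunit of ON bipolar cells, rose by 2.99, Car8 was at least 2.21-fold higher, Pcp2 rose by 1.44, and Trpm1 fell by 1.36 with the probe used, while another of its probes had a value of 0.81. Of the genes shared by bipolar cells 7 of 10 rose and 2 fell, also adjusted over the list alone (median 0.94, adjusted p = 0.0216, and adjusted p = 0.281 with an estimated correlation). Gnb3 rose by 2.79 and Lrtm1 at least 2.65-fold. OFF cone bipolar genes had a median of 0.42, with 3 higher and 1 lower of 10, also adjusted over the list alone (adjusted p = 0.296). Cabp2 was at least 2.86-fold higher, Tacr3 rose by 1.26 and Fezf2 fell by 1.39. Tfap2b, an amacrine cell factor, rose 4.60-fold (2.20, SE 0.15), and Rlbp1 and Apoe, genes of Mueller glia, rose by 2.32 and 1.19.

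Genes of dividing and progenitor cells fell over the same step. All 29 cell cycle genes fell (median -1.50, adjusted p = 6.38e-13, and adjusted p = 0.405 with an estimated correlation). Mcm5 fell by 2.04, Mcm3 by 2.03 and the proliferation marker Mki67 by 1.30. Progenitor genes fell in 8 of 12, also adjusted over the list alone, including the Wnt modulator Sfrp2 by 3.17, Hes1 by 2.40 and Sox2 by 1.30. Their median was -1.05 (adjusted p = 0.000234, and adjusted p = 0.405 with an estimated correlation). Stress and heat shock genes fell in 8 of 12 (11 adjusted over the list alone), led among those that passed by Chac1 (-1.47). Their median was -0.85 (adjusted p = 0.00012, and adjusted p = 0.281 with an estimated correlation). Imprinted genes fell in 7 of 15 and rose in 1, also adjusted over the list alone, with values of -1.74 for Plagl1 and -1.42 for H19. Their median was -0.43 (adjusted p = 0.0319, and adjusted p = 0.281 with an estimated correlation). Pou4f2, a ganglion cell factor, fell 7.17-fold (-2.84, SE 0.57), while the ganglion cell list had 4 genes higher and 7 lower of 16 (4 and 10 adjusted over the list alone; adjusted p = 0.2).

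The limma test of DD23 with DD16 gave 4553 genes higher and 5170 lower, 1363 and 857 of them by at least 2-fold, and 9721 of the 9723 went the same way in every line. Within the slide of WT and Isl1KO 6596 passed. Of the lists 10 passed with the preset correlation and 0 with the estimated one.

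**Figure D2:**
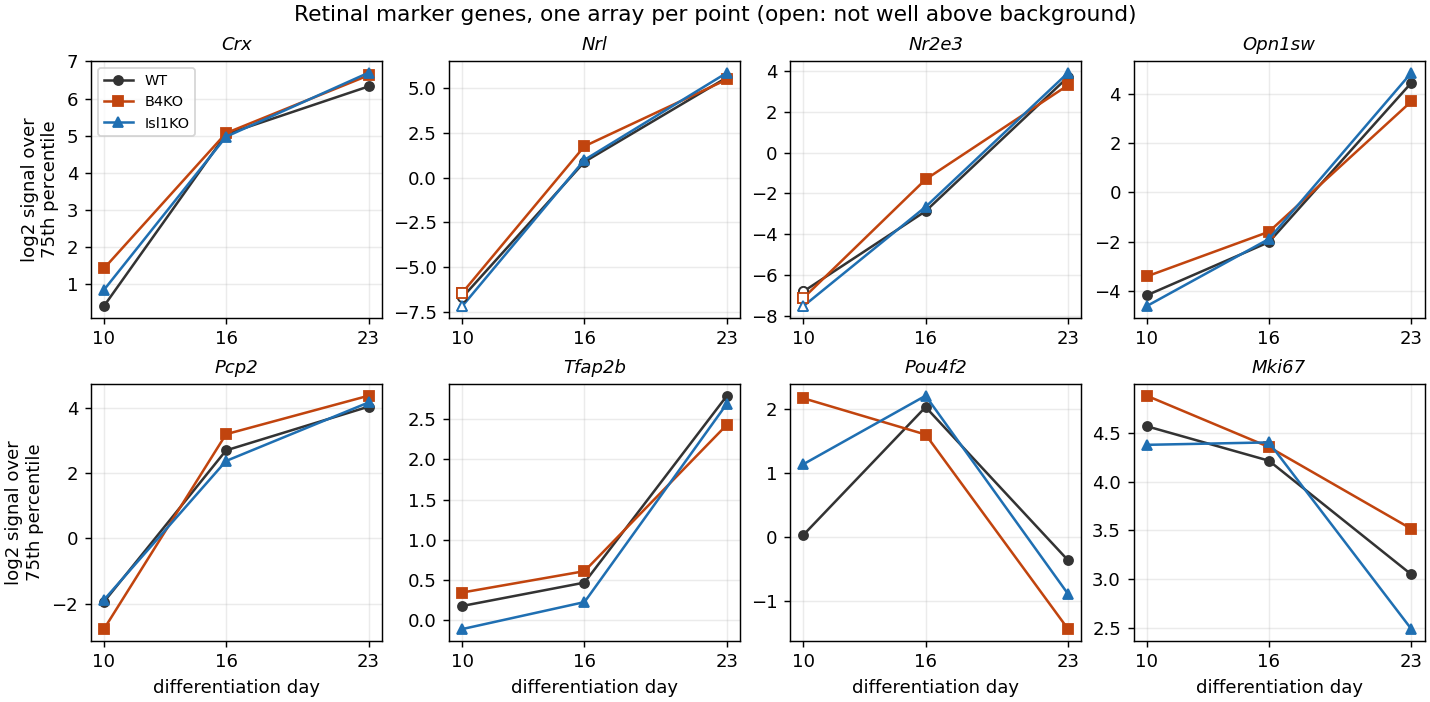
Log2 signal relative to the array's 75th percentile (y axis) of 8 marker genes by differentiation day (x axis), 1 point per array and a colour per line, with open symbols where not well above background. Crx rose by 4.13 from DD10 to DD16 in the model of all arrays, and Mki67 fell by 1.30 from DD16 to DD23.

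Isl1KO organoids differed from WT in Cdkn1c, an imprinted gene, that is, one expressed from 1 parental copy, and some other imprinted genes had large values that did not pass over all genes. Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, rose 116-fold (6.85, SE 0.22, adjusted p = 0.00184, n = 3 days per line), with values of 7.12, 6.74 and 6.69 at DD10, DD16 and DD23 (chromosome 7, 150644297 to 150644356). Meg3, Rian and Mirg, maternally expressed RNAs of a single imprinted locus on chromosome 12, had values of 5.69 (SE 1.11), 4.24 (SE 0.53) and 4.20 (SE 0.43) that did not pass over all genes (adjusted p = 0.362, 0.214 and 0.173). Adjusted over the list alone, 7 of 15 imprinted genes were higher, the others being H19 (1.35), Plagl1 (0.77) and Igf2 (0.61), and Dlk1 (-0.71) and Impact (-0.29) were lower. The median of these 15 was 0.17 and their mean 1.51 (adjusted p = 0.000155, and adjusted p = 0.163 with an estimated correlation). In a wider list of 39 imprinted genes written after the first results, adjusted over that list alone, 6 were higher, Nap1l5 (4.60) and H19 among them. There Inpp5f (-1.04) and Impact were lower, and Plagl1, Igf2 and Dlk1 did not pass.

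Ganglion cell genes had negative values in 15 of 16 (median -0.57, adjusted p = 1.26e-08, and adjusted p = 0.163 with an estimated correlation). None passed over all genes and 5 were lower adjusted over the list alone: Thy1 (-1.83), the neurofilament Nefl (-1.45), the vesicular glutamate transporter Slc17a6 (-0.94), Rbpms (-0.84) and Ebf3 (-0.57). Pou4f2 went the other way, by 0.25. Pigment epithelium genes were negative in all 14 (median -0.41, adjusted p = 1.63e-06, and adjusted p = 0.349 with an estimated correlation). The melanin genes Tyr, Dct, Pmel and Mlana and the retinol enzyme Rdh5 were lower adjusted over the list alone, while none passed over all genes. Starburst amacrine genes, of the cholinergic cells that need Isl1, were negative in all 6 (median -0.86, adjusted p = 0.015, and adjusted p = 0.570 with an estimated correlation). The choline transporter Slc5a7 (-1.92) and Slc18a3 (-1.46) had the lowest values, which no adjustment called. In B4KO all 6 were negative too (median -1.07, adjusted p = 0.346), and Isl1KO minus B4KO had a median of -0.07 (adjusted p = 0.887).

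Progenitor genes had a median of 0.34 (adjusted p = 0.0343, and adjusted p = 0.729 with an estimated correlation), and Fgf15 a value of 0.56. The difference was largest at DD10, where the list's median signal was 3.83 in Isl1KO and 2.98 in WT. It was 4.03 and 3.71 at DD16, and 2.44 and 2.55 at DD23. In B4KO the progenitor list had a median of 0.51 relative to WT and a median signal of 4.02 at DD10. Isl1KO minus B4KO had a median of -0.15, so the difference from WT was not particular to Isl1KO. Lens genes had a median of 0.30 (adjusted p = 0.0343, and adjusted p = 0.349 with an estimated correlation), and Cryaa was higher adjusted over the list alone (1.03). Neural crest and oligodendrocyte genes had a median of -0.34 (adjusted p = 0.0401, and adjusted p = 0.349 with an estimated correlation), with Sox10 lower adjusted over the list alone (-1.34). Mesenchyme genes had a median of -0.33 (adjusted p = 0.0421, and adjusted p = 0.666 with an estimated correlation), and within the slide of both lines adjusted p = 0.0894. In other lists Onecut3 of horizontal cells (1.95) was higher and Cx3cr1 of microglia was lower (at least 1.47-fold) adjusted over the list alone.

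Cdkn1c was the only gene of 23594 past the threshold, while 1924 had an unadjusted p under 0.05 against 1179.7 expected by chance. Limma called 11 genes with normexp correction, 14 with trend and robust options and 4548 with no filter on dim probes (4386 lower). That last count takes in dim spots held at a substitute value. The lowest values were lower on the Isl1KO arrays than on the WT arrays of the same day. Both lines were on the same slide, and within it limma called 3 genes, Cdkn1c (adjusted p = 0.00502), Mirg (adjusted p = 0.00798) and a transcript of chromosome 12 between Meg3 and Rian (4.90, adjusted p = 0.00502). Without the WT sample at DD16 or at DD23, or without either of those days, limma called 0 genes; the Cdkn1c difference rests on 1 probe. Of the lists 8 passed with the preset correlation and 0 with the estimated one. With 1 line per genotype, none of these differences can be told apart from a difference between lines.

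**Figure D3:**
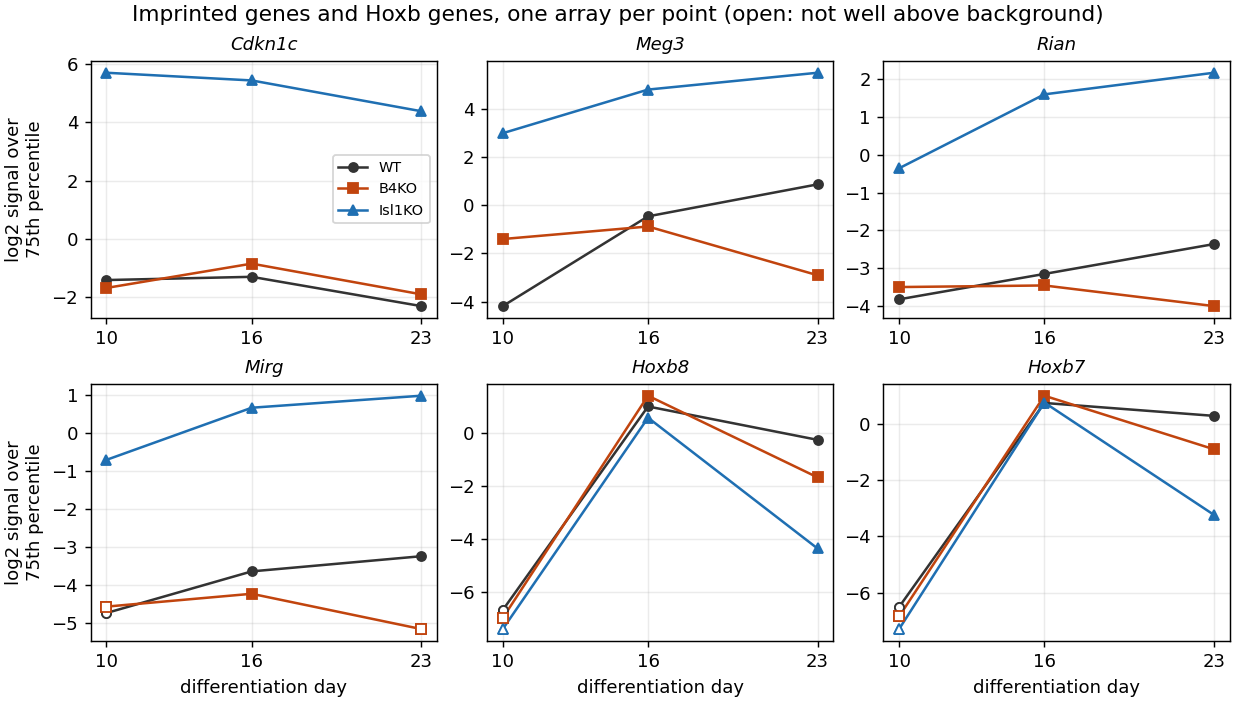
Log2 signal relative to the array's 75th percentile (y axis) of 4 imprinted genes (Cdkn1c, Meg3, Rian, Mirg) and of Hoxb8 and Hoxb7 by differentiation day (x axis), 1 point per array and a colour per line, with open symbols where not well above background. Isl1KO lay above WT by 7.12, 6.74 and 6.69 for Cdkn1c, and Hoxb8 and Hoxb7 came up at DD16 in every line.

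B4KO organoids differed from WT chiefly by lower signal, most often in dimmer genes. The largest falls were in Bex6 (at least 7.03-fold), Prl3b1 of the prolactin family (-2.87, SE 0.65), R3hdml (at least 3.24-fold), the nonsense-mediated decay gene Smg8 (at least 2.81-fold), coagulation factor F7 (at least 1.97-fold) and the alcohol dehydrogenase Adh1 (at least 1.64-fold). Prl3b1 was well above background on no B4KO array, but the bound left its values unchanged, so a fitted value is given. By day it was -4.65, -2.42 and -1.55 at DD10, DD16 and DD23. Rises were led by the inflammasome sensor Nlrp1b (at least 2.62-fold), the efflux pump Abcb1b (at least 1.17-fold), Slc27a6 (1.36, SE 0.36), Zfp69 (at least 1.20-fold), the MAP kinase phosphatase Dusp9 (1.08, SE 0.25) and Tatdn2 (1.04, SE 0.25; n = 3 days per line). Of these rises all but Nlrp1b lost their call in 8 or more alternatives. Cell cycle genes had positive values in 28 of 29 (median 0.28, adjusted p = 0.00371, and adjusted p = 0.858 with an estimated correlation), of which Pcna passed over all genes (0.45) and none adjusted over the list alone. The list was bright, with median signals of 3.43, 2.94 and 1.88 in B4KO at DD10, DD16 and DD23. Of 10 groups of all genes by signal, groups 9 and 10, the brightest, had medians of 0.11 and 0.13. Camera did not match genes on signal.

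Lens genes fell in 4 of 11, also adjusted over the list alone (Cryaa -1.65). Their median was -0.46, or -0.19 with dim members at their bound (adjusted p = 0.129 by camera). They were dim, with median signals from -4.85 to -3.16 by array. In the 3 dimmest of 10 groups of all genes by signal, medians were -0.49, -0.36 and -0.23. Of those genes 638 of 2360, 696 of 2359 and 673 of 2359 were called lower, so the lens values lay near those of other dim genes. Pluripotency genes fell in 4 of 8, also adjusted over the list alone (Utf1 -1.21, Tdgf1 -1.04, Sall4 -0.83 and Pou5f1 -0.64). Their median was -0.52 (adjusted p = 0.145 by camera). Among OFF cone bipolar genes Cabp2 and Grik1 fell by 1.09 and 0.95, and Syt2 fell too, also adjusted over the list alone (median -0.24, adjusted p = 0.519). Grik1 differed by -1.10 at DD10 already. Rod and ON cone bipolar genes had a median of -0.03 (2 lower of 14, and 1 adjusted over the list alone; adjusted p = 0.954).

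By limma 942 genes rose and 4251 fell, 17 and 1716 of them by at least 2-fold, all in the same direction at the 3 days. Of the lower genes 2924 were well above background on all 9 arrays and 827 on no B4KO array. With cyclic loess 1983 rose and 2859 fell, and with the brightness and GC trend removed 1501 and 2645 did, both added after seeing the data. Without the WT sample at DD10 or at DD23 3417 passed in either case, and without DD10, DD16 or DD23 2871, 3116 and 2530 did. B4KO was alone on its slide and was 1 line. None of these differences can be told apart from a difference between slides or between lines. Over 10 groups of genes ordered by signal, the median difference ran from -0.49 in the dimmest to 0.13 in the brightest. Spike-in RNAs were added in equal amount to every sample, and 8 had a mean signal over the limit of signal well above background. The dimmest of these 8 read -0.78 on that slide relative to the other, and the others from -0.02 to 0.19. The dimmer spike-ins E1A_3 and E1A_a104 lay below that limit and were left out. For 109 genes lower by a log2 of 1 or more that had a second probe, the second probe gave a median of 0.123 of the fall of the first.

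**Figure D4:**
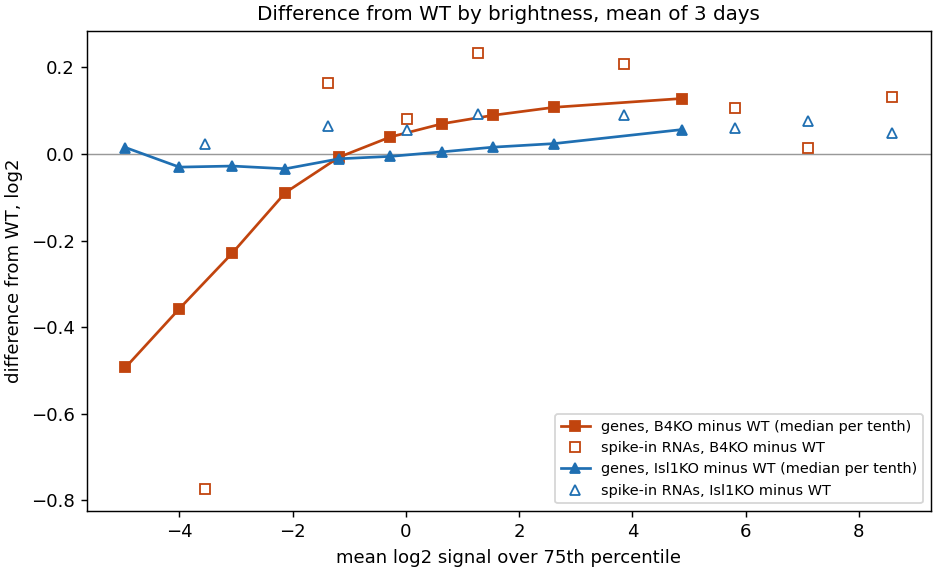
Median log2 difference from WT (y axis) of B4KO and of Isl1KO over 10 groups of genes ordered by mean log2 signal (x axis), with the spike-in RNAs as single points. The B4KO line runs from -0.49 in the dimmest group to 0.13 in the brightest, while the Isl1KO line stays between -0.03 and 0.06.

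Compared directly, which tests whether the effects of the knockouts differ, some imprinted genes were higher in Isl1KO than in B4KO. Cdkn1c was higher by 101-fold (6.66, SE 0.22, n = 3 days per line), Meg3 by 71.3-fold (6.16, SE 1.11), Mirg by 4.98 (SE 0.43) and Rian by 4.78 (SE 0.53). Nap1l5, an imprinted gene of the nucleosome assembly family, was at least 21.9-fold higher. The imprinted list had 5 of 15 higher and 2 lower, also adjusted over the list alone, and did not pass (median 0.29, adjusted p = 0.254). Bex6, dim in B4KO, was at least 6.99-fold higher. Lower in Isl1KO were Isl1 itself (-1.79, SE 0.33, with -0.34 for its other probe), the neurofilament Nefl (-1.63, SE 0.33), Irx2 (-1.69, SE 0.41), Fut1 (-1.59, SE 0.34), Nlrp1b (at least 4.22-fold) and Cx3cr1 (at least 1.27-fold).

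Cell cycle genes were negative in all 29 (median -0.38, adjusted p = 5.55e-05, and adjusted p = 0.850 with an estimated correlation), of which Pcna passed (-0.58). Lens genes were higher in 6 of 11, also adjusted over the list alone, with Cryaa higher by 2.69. Their median was 0.72, or 0.69 with dim members at their bound (adjusted p = 0.0138, and adjusted p = 0.781 with an estimated correlation). Dim genes of all kinds read lower in B4KO and bright genes somewhat higher, as given above. Camera did not match genes on signal, which limits the results of both the lens and the cell cycle list. Ganglion cell genes were lower in 3 of 16 and higher in 1, also adjusted over the list alone (median -0.30, adjusted p = 0.0316, and adjusted p = 0.824 with an estimated correlation). Pigment epithelium genes were lower in 3 of 14 and higher in 1, likewise (median -0.42, adjusted p = 0.0316, and adjusted p = 0.824 with an estimated correlation). Limma called 4260 genes higher and 897 lower in Isl1KO, against 2912 and 2180 with cyclic loess and 2718 and 1748 with the brightness and GC trend removed, both added after seeing the data. Without the Isl1KO sample at DD16 3288 passed, and without DD16 or DD23 2683 and 2939 did. The slides differed here too, so these counts include any difference between slides.

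Bipolar cell genes were the aim of the design. At DD23 the medians of their 3 lists ran from -0.55 to 0.20 relative to WT, and whether the lists differed was not tested. Rod and ON cone bipolar genes had a median difference of 0.10 in B4KO (percentile 88.0 among matched random lists) and 0.08 in Isl1KO (percentile 89.0), which turned to -0.03 in Isl1KO with genes measured on all 9 arrays. Pcp2 lay at 0.34 and 0.13 and Gng13 at 0.31 and 0.35, while Prkca, the classical rod bipolar marker, lay at -0.20 and -0.03. The shared bipolar genes had medians of 0.10 (percentile 66.2) and 0.20 (percentile 98.8), with Cabp5 at -0.72 and -0.41. OFF cone bipolar genes had medians of -0.55 in B4KO (7 of 10 negative, percentile 4.7; -0.33 with normexp correction) and -0.08 in Isl1KO (percentile 31.8). Neto1, a kainate receptor partner, differed by -1.28 and -1.90, Irx5 by -0.78 and -0.91, Grik1 by -0.82 and 0.13 and Cabp2 by -0.67 and -0.05. At DD10 and DD16 the OFF cone bipolar median of B4KO stood at -0.46 (percentile 9.5) and -0.26 (percentile 8.2), so it was low before DD23 too. B4KO cannot be told apart from its slide. All of these values compare single arrays and have no test. Vsx1 and Grm6, markers of OFF and ON bipolar cells, were too dim to be tested.

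At DD10 both knockouts had more progenitor signal than WT, with list medians of 1.18 in B4KO and 0.80 in Isl1KO. Six6 differed by 1.59 and 0.86 and Rax by 1.25 and 1.05. Forebrain genes went both ways at that day, with medians of -0.68 and -0.65 and 7 and 6 of 11 negative, such as Emx2 by -1.32 and -1.17 and Tbr1 by -1.29 and -1.11. The p53 targets had medians of -0.62 and -0.59 at DD10 and 0.46 and 0.47 at DD23, with Eda2r at -1.07 and -1.26 and then 1.09 and 1.14. The starburst list stood at -0.53, 0.17 and -2.02 in Isl1KO at DD10, DD16 and DD23 and at -1.32, -0.73 and -0.73 in B4KO. In Isl1KO at DD23 the acetylcholine transporter Slc18a3 lay at -3.83 and Megf11 at -2.29. Photoreceptor genes at DD23 had medians of 0.30 for rods, 0.29 shared and 0.36 for cones in Isl1KO, and -0.23, -0.02 and -0.03 in B4KO. Ganglion cell genes had medians of -0.61, -0.41 and -0.55 at DD10, DD16 and DD23 in Isl1KO, and -0.13, -0.01 and -0.50 in B4KO. Cell cycle genes at DD23 lay at 0.42 in B4KO and -0.52 in Isl1KO, and mesenchyme genes at -0.77 and -1.44. At DD16 the median mesenchyme signal was higher in Isl1KO (-1.79) than in WT (-2.34), and lower in B4KO (-2.60). WT alone is the reference for both knockouts, so a WT sample that stands apart moves both values together.

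No gene had a late effect, that is, a difference at DD23 that departed from DD10 and DD16: limma called 0 in B4KO (1429 at unadjusted p under 0.05, smallest adjusted p = 0.278) and 0 in Isl1KO (1161, smallest adjusted p = 0.757). In simulated data the late term for Isl1KO recovered 0% of genes altered by a log2 of 1 or 2 and 50% of those altered by 4, so a smaller late effect was not detectable with these arrays.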

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

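The tests of the spike-in RNA on the slide of B4KO, of the lower genes with the trends removed, of other probes of the imprinted genes, of another cell type and of silencing beside Meg3 were chosen only after the result was seen.

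The direct test of Isl1KO with B4KO gave 5157 genes, a count that includes any difference between slides, since B4KO was alone on its slide. Isl1KO minus B4KO was 6.66 for Cdkn1c, 6.65 for Nap1l5, 6.16 for Meg3, 4.98 for Mirg, 4.78 for Rian and 3.81 for Bex6. It was -4.35 for Nlrp1b, -2.38 for Cx3cr1, -1.79 for Isl1, -1.69 for Irx2, -1.63 for Nefl and -1.59 for Fut1. For Nap1l5, Bex6, Nlrp1b and Cx3cr1 the dimmer line was well above background on no array, so these are fitted values and not bounds. In the control spots, which no comparison used, the spike-in RNA E1A_a107 read -0.78 on the slide of B4KO relative to the other.

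Other splits of the same arrays were counted for each model. Of 36 splits into genotypes within days, 1 (the real one) gave 4772 genes or more and the highest other gave 4192. The 3 others that kept the B4KO arrays together gave 4038 to 4192 and the 32 that split them 0 to 1. The count thus follows B4KO or its slide, and these splits cannot exclude chance for an effect of genotype. Of 36 splits into days within lines, 1 (the real one) gave 15496 or more and the highest other gave 2387. That argues against chance, though 1 of 36 is the smallest share such splits can give. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05; the real split was the 1 that gave as many, with 5193, 1, 5157, 9606 and 9723 genes for B4KO with WT, Isl1KO with WT, Isl1KO with B4KO, DD16 with DD10 and DD23 with DD16, and the highest other was 0 for each.

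Of the genes changed in B4KO, 4251 of 5193 were lower than in WT. Trends over probe brightness and GC content could not be decided: with them removed 2563 of the 4251 stayed lower (60.3%) and their median went from -0.90 to -0.61, between the bounds set, while the bound first written counted both directions and was met (4146 genes) because the higher genes grew from 942 to 1501. Weak signals reading lower on that slide may contribute, since the spike-in E1A_a107 read -0.78 there (SD within slides 0.22) and 0.02 in Isl1KO minus WT. It was the dimmest of the 8 spike-ins above the background limit, however, and the others read from -0.02 to 0.19. The dimmer E1A_3 and E1A_a104 were not used. Signals of single probes may contribute too, since the second probe gave a median of 0.123 of the first probe's fall over 109 genes, against 0.910 and 0.907 for genes that fell between days. B4KO and its slide cannot be told apart, so an effect of the lost Bhlhe23 stays open and untested.

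Of 15 imprinted genes 7 were higher in Isl1KO than in WT and 2 lower adjusted over the list alone, and over all genes Cdkn1c alone passed. For Meg3, Mirg, H19, Igf2 and Plagl1 the other probes gave a median of 0.875 of the first probe's difference (lowest 0.516, Plagl1), and those of Meg3 and Mirg were higher by 3.99 or more, which argues against single probes by the bound used for B4KO, taken up here because a first bound was out of reach of small differences; Cdkn1c and Rian have 0 other probes and stay open. Cells of another type could not be decided: 3 genes outside the imprinted lists were higher by a log2 of 3 or more at all 3 days against 4 within them, which lay on the bound first written for excluding such cells, and a count of top genes excludes nothing; 1110006E14Rik and another transcript lie among the Meg3, Rian and Mirg probes on chromosome 12, and Vax2os (3.20, 5.19 and 5.01) on chromosome 6. Silencing of the Meg3 side of the locus in the other lines could not be decided, since its paternally expressed neighbours had a median of -0.11 (Dlk1 -0.71, Dio3 0.49; Rtl1 not tested). A change of imprinting that arose in 1 line in culture is a candidate explanation, which 1 line per genotype cannot separate from the loss of Isl1.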

How the results depend on the processing

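The alternatives that removed the brightness and GC trend, applied cyclic loess or set dim list members at their bound were chosen only after the result was seen. Over all alternatives the gene and list counts stayed within 1.5 times the reported count in 151 cases and moved further in 35; named genes kept their side of the threshold in 887 cases, lost it in 109 and reversed in 0; list medians by day moved by less than the spread of random lists in 1117 cases and more in 137, and targeted genes in 32 and 4.

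Isl1KO with WT gave 11 genes with normexp correction, 4548 with no filter on dim probes (4386 lower), 14 with trend and robust options, 3 on the slide of both lines, and 0 without DD16 and 0 without DD23. With no filter, probes held at the substitute value for dim spots enter. The lowest deposited value was 0.00596, 0.00623 and 0.00518 in Isl1KO at DD10, DD16 and DD23, and 0.00981, 0.01 and 0.0069 in WT. The 4386 lower genes therefore include any such offset and do not measure the knockout. The F test over genotypes gave 9015 with no filter, 2020 without the day term, and 2576, 2312 and 2225 without DD10, DD16 and DD23. B4KO with WT gave 2189 without the day term and 2871, 3116 and 2530 without those days; Isl1KO with B4KO gave 2366, and 3310, 2683 and 2939. DD16 with DD10 gave 6172 without the genotype term and 4899 on the slide of WT and Isl1KO. The cause of these changes was not tested, and fewer arrays may contribute where a day or slide is left out. With an estimated correlation, camera called 0 lists in B4KO with WT, 0 in Isl1KO with WT, 0 in Isl1KO with B4KO, 0 in DD16 with DD10 and 0 in DD23 with DD16. The OFF cone bipolar median of B4KO at DD23 was -0.33 with normexp correction, and the rod and ON cone bipolar median of Isl1KO at DD23 was -0.03 with genes measured on all 9 arrays.

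Leaving out each array in turn gave 3417 to 4621 genes for B4KO with WT, 0 (without WT at DD16 or DD23) to 2 for Isl1KO with WT, 3288 to 4789 for Isl1KO with B4KO, 5899 to 9079 for DD16 with DD10, 6510 to 9337 for DD23 with DD16, 3178 (without B4KO at DD23) to 4382 over genotypes and 12901 to 14311 over days; late effects stayed at 0. Calls lost in B4KO with WT were those of Dusp9 (12 alternatives), Slc27a6 (11), Tatdn2 (10), Abcb1b and Zfp69 (8 each), R3hdml (6) and Prl3b1 (5). In Isl1KO with B4KO they were those of Cx3cr1 (12), Irx2 (10), Fut1 (8), Nefl (7), Isl1 (6) and Meg3 (2), and in Isl1KO with WT that of Cdkn1c (4). Cdkn1c was the gene called with quantile normalization, the deposited table and loess. Genes near the background limit what these arrays show: signal over background held for 57.3% to 67.8% of gene spots.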

Other observations

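The tests of the retinoic acid response and of hindbrain or spinal cord cells were chosen only after the result was seen.

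Other cell types changed over the days with less common direction. From DD16 to DD23 amacrine genes rose in 8 of 16 and fell in 2, also adjusted over the list alone (median 0.65, or 0.61 with dim members at their bound; adjusted p = 0.0671), led by Tfap2a (2.54) and C1ql2 (at least 3.13-fold), while at DD16 Ptf1a, the factor that directs progenitors to amacrine and horizontal fates, had been at least 54.6-fold higher than at DD10 and Prdm13 54.3-fold. Mueller glia genes rose in 5 of 15 and fell in 5 (median -0.18, adjusted p = 0.995), since Rlbp1 and Apoe rose as Hes1 and Sox2, which progenitors share, fell. Neurogenic genes rose in 3 of 14 and fell in 6 (median -0.37, adjusted p = 0.294), starburst genes had a median of 1.22 (Megf10 rose by 1.72; adjusted p = 0.23) and horizontal cell genes -0.77 (adjusted p = 0.201), with Lhx1 lower at DD16 than at DD10 by -1.31.

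Forebrain genes fell in 5 of 11 from DD16 to DD23 (7 adjusted over the list alone; median -0.72, adjusted p = 0.0704), Dlx2 by 2.01 and Dlx1 by 1.88, after Emx1 (-2.93) and Bcl11b (-2.52) had fallen by DD16. Medians from DD16 to DD23 were 0.16 for lens, -0.02 for mesenchyme (Col1a1 rose by 1.85), -0.10 for pluripotency genes, 0.03 for endoderm, 0.30 for skeletal muscle, 0.16 for endothelium and blood cells, 0.01 for neural crest, -0.06 for pigment epithelium, -0.03 for hypoxia and glycolysis, -0.21 for immediate early genes, -0.18 for p53 targets, 0.00 for the interferon response (or 0.06 without a member dim on both days) and -0.05 for Y-linked genes, and none of these lists passed. The Y-linked Kdm5d was lower in B4KO than in WT (-1.36, SE 0.14), while Ddx3y and Uty had positive values.

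Hoxb genes were high at DD16: 7 of 8 tested genes of cluster b rose from DD10 (median 6.39) and 7 fell again by DD23 (median -2.76), in all lines. The size of the fall differed between lines. Hoxb7 went from 0.748 to 0.289 in WT, from 1.005 to -0.898 in B4KO and from 0.763 to -3.229 in Isl1KO. Hoxb8 went from 1.008 to -0.249, from 1.413 to -1.662 and from 0.584 to -4.342. Hoxb9 fell far in WT as well (-1.355 to -5.028). Cells of hindbrain or spinal cord could not be decided: 3 of 29 Hox genes outside the cluster were well above background on all DD16 arrays, under the bound first written for excluding such cells, but genes near background exclude nothing, 3 of 5 tested rose (Hoxc4 by 5.45), and a list of hindbrain and spinal cord genes went both ways (median -0.17, 1 higher and 3 lower of 8). A response to retinoic acid could not be decided either: other responsive genes had a median of 0.15, under the bound first written for excluding it, but 6 of 15 rose and 3 fell, Rarb by 5.26 among the rises, and a median over genes that go both ways decides nothing. Cyp26a1 and Cyp26b1, which degrade retinoic acid, went the way of the Hoxb genes. From DD10 to DD16 Cyp26a1 had a value of 2.35 and Cyp26b1 a larger positive one, and both fell at DD23. Rarb fell at DD23 as well, but over that step 4 genes of its list rose and 3 fell. Exposure of the cultures to retinoic acid around DD16 is a hypothesis that these data leave open and do not test. The added lists of Hox genes outside cluster b, paternally expressed genes beside Meg3 and other imprinted genes had DD16 minus DD10 medians of 1.10, 1.17 and -0.12.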
